A study of Homo sapiens with 6 samples.

How the data were processed

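The data are 6 arrays of RNA from Jurkat cells, 3 of cells in suspension and 3 of cells kept for 3 h in type I collagen at 1.7 mg/mL. Per the labels' protocols, the RNA was labelled with a whole-transcript GeneChip kit. The deposited values are log2 expression per probe set, 1 column per array. RMA and the Transcriptome Analysis Console made them, per the submitters' processing notes, with versions, probe annotation and genome build not given in the sources used here. RMA subtracts background, puts arrays on a common distribution and summarises the probes of a set. This shrinks differences of dim probe sets and can hide a shift of the whole transcriptome. Detection flags and background levels were not used here, so a level near the array's floor cannot be told from no expression. Array medians lay between 5.55 and 5.64, and the values were used as deposited. There were 0 columns of per-sample values beyond the 6.

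Of 21448 probe sets, the platform's gene table paired 17709 with 1 gene symbol, 0 with several and 3739 with none. All 17709 matched the RefSeq table of assembly GRCh38.p14 by gene identifier, and 0 symbols needed an update. For 20 genes with over 1 probe set, the probe set with the highest mean over the 6 arrays was kept, which left 17687 genes; the probe sets of 7 of these 20 differed in sign. The RefSeq table served for names, gene spans, chromosomes and numbers of neighbours within 500 kb. The files name no build, so no coordinates are given.

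Groups and replicate numbers came from the sample titles. The test, the lists, the rule for named genes and a set of alternatives were fixed before the data were examined. The main test was limma 3.58.1 (R 4.3.3), lmFit and eBayes with no block and no filter on dim probe sets, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The spread was estimated with 4 residual and 6.79 prior degrees of freedom. The 36 gene lists were tested with camera at a preset correlation of 0.01 and a minimum of 5 measured genes, adjusted over the lists, beside camera with an estimated correlation and fry. The lists held 797 genes, of which 707 were measured. The result of 1 of the lists is not reported here. The 7 marker lists were tested the same way and adjusted among themselves. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

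Genes were named by rule. In each direction these were the 15 largest changes past the threshold with groups that did not overlap, or, where none passed, the 5 genes of smallest p, said not to pass. From each list up to 4 members of smallest p could be named, and all T cell markers. Genes past the threshold with the block, and those named under settings chosen later, were named after their values were seen.

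The titles number the replicates 1 to 3 in both groups, so the numbers were checked for pairing. After subtracting group means, same-numbered arrays correlated at 0.521, 0.120 and 0.337 for numbers 1, 2 and 3. As all 3 lay over 0.1, the threshold set in advance, the numbers were taken to pair the samples. The basis is weak for number 2: suspension 2 correlated better with 3D 3 (0.230), and 3D 2 with suspension 3 (0.149). That crossed matching, with number 1 kept, also has all 3 correlations over 0.1 (0.521, 0.230 and 0.149). The rule therefore does not single out the replicate numbers, and every result with the block rests on this choice. These correlations were first seen together with a count of calls with the block over all probe sets, so the decision followed the rule but was not blind to that count. Results with the replicate number as a block are given where they change a call. For fry's mixed test, described below, only the number of lists called with the block is given. With the block the fit had 2 residual and 9.78 prior degrees of freedom.

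The tests were checked on simulated data drawn from each fit's means and from its spreads after sharing between genes, with 10 simulations of 200 changed genes each. With the block these means held the replicate effects. The simulations thus took the shared spread and the pairing as true and cannot check them. Sizes ran from 0.5 to 2 log2, and noise was drawn independently for each gene, unlike real arrays. In the real data 23 genes differed by at least 2-fold and 0 passed without the block. The shares found below need not hold there, and 0 calls do not show that 2-fold changes are absent. Over 17687 genes, the fit without the block found 10% of planted changes of 0.5 log2, 86.6% of changes of 1 and 99.6% of changes of 1.5, with 10.4 false calls per simulation. With the replicate block it found 29.8%, 99.4% and 100% at these sizes, with 12 false calls. With the block and the 8342 genes of mean at or above 6, it found 62.6% at 0.5 and 100% at 1, with 8.2 false calls. A shift of 0.3 planted in the list of immediate early genes was called by camera in 10 of 10 simulations, with and without the block, and in 0 of 10 with an estimated correlation, so a miss with an estimated correlation carries little information. As simulated genes were independent, this does not show how often the preset correlation calls lists whose members vary together.

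Alternatives covered the replicate block, 2 filters on dim probe sets, 3 scalings, 2 variance models, each array left out in turn, averaging of probe sets, all probe sets, fold thresholds, an equal-variance test and other list tests. After the results were seen, 14 further settings with the block were run for the gene count, as were fits with each array's trend on span and neighbours removed. Array scan dates were not used here, so a batch effect of hybridisation could not be tested.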

Results

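Jurkat cells, a line grown from a human T cell acute lymphoblastic leukaemia (T-ALL), were profiled on 6 Affymetrix whole-transcript arrays. Cells of 3 arrays stayed in suspension for 3 h, and cells of the other 3 spent the same time in a gel of bovine type I collagen at 1.7 mg/mL, called 3D here. The labels call the samples of each group biological replicates and number them 1 to 3 without saying what separated them. The p-values of limma for single genes thus measure the spread between these samples. Camera with the preset correlation weighs a list's genes against the other genes, so its p-values do not measure how a list varies between samples. Expression is given as the deposited log2 value, which ran from 1.97 to 13.58. Array medians over all probe sets lay between 5.55 and 5.64. Pairwise correlations between arrays over 17687 genes ran from 0.971 to 0.991, and no pair of arrays held the same values. The first principal component carried 42.8% of the variance, with suspension replicate 1 at one end (score -40.4) and 3D replicate 3 at the other (score 29.2). The number of arrays limits the precision of every value.

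The comparison asked which transcripts differ after 3 h in collagen. No gene passed the test fixed for the comparison, and the largest differences measured were higher values in 3D. ARRDC3, an arrestin-domain gene and a known target of FOXO transcription factors, measured 5.87 ± 0.19 (SD, n = 3) in suspension and 7.16 ± 0.32 (SD, n = 3) in 3D. That is a log2 difference of 1.28 ± 0.20 (SE), or 2.44-fold. The next smallest p-values on the higher side belonged to ODF2L, a centriole protein gene (log2 difference 1.11 ± 0.18 SE), NEMF, a factor of ribosome quality control (1.03 ± 0.17), TBC1D32, a gene of cilium assembly (0.97 ± 0.16), and ANKRD36C (1.02 ± 0.17). On the lower side stood SLC7A4 (-0.76 ± 0.15), NEFH, the heavy neurofilament gene (-0.72 ± 0.15), JUNB, an AP-1 transcription factor gene (-0.77 ± 0.17), FIBCD1 (-0.78 ± 0.18) and MPST, an enzyme of sulfur metabolism (-0.76 ± 0.17). All 10 differed in the same direction in the 3 replicates, with no overlap between groups. None passed: limma gave an adjusted p of 0.293 for each of the 5 higher genes, and of 0.330 to 0.347 for the lower ones.

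Over all 17687 genes limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.293. At an unadjusted p under 0.05 there were 1745 genes, 1043 higher and 702 lower in 3D. Chance alone gives 884 on average. After quantile normalization once more there were 893 higher and 900 lower. With 1 array left out the number at an unadjusted p under 0.05 (limma) varied. It ran from 1075 without 3D replicate 3 (683 higher, 392 lower) to 2007 without 3D replicate 1 (1169 and 838). The groups did not overlap for 2886 genes, or 16.3%, against 10% by chance on average. Genes of the same arrays vary together, so a single split of the arrays can lie far from such averages. Over the other splits of 3 against 3, the number at an unadjusted p under 0.05 (limma) ran from 231 to 1947. The share without overlap was not computed for them. A difference of at least 2-fold was measured for 23 genes, all higher in 3D. An equal-variance test without moderation, Benjamini-Hochberg adjusted, also called 0.

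**Figure D1:**
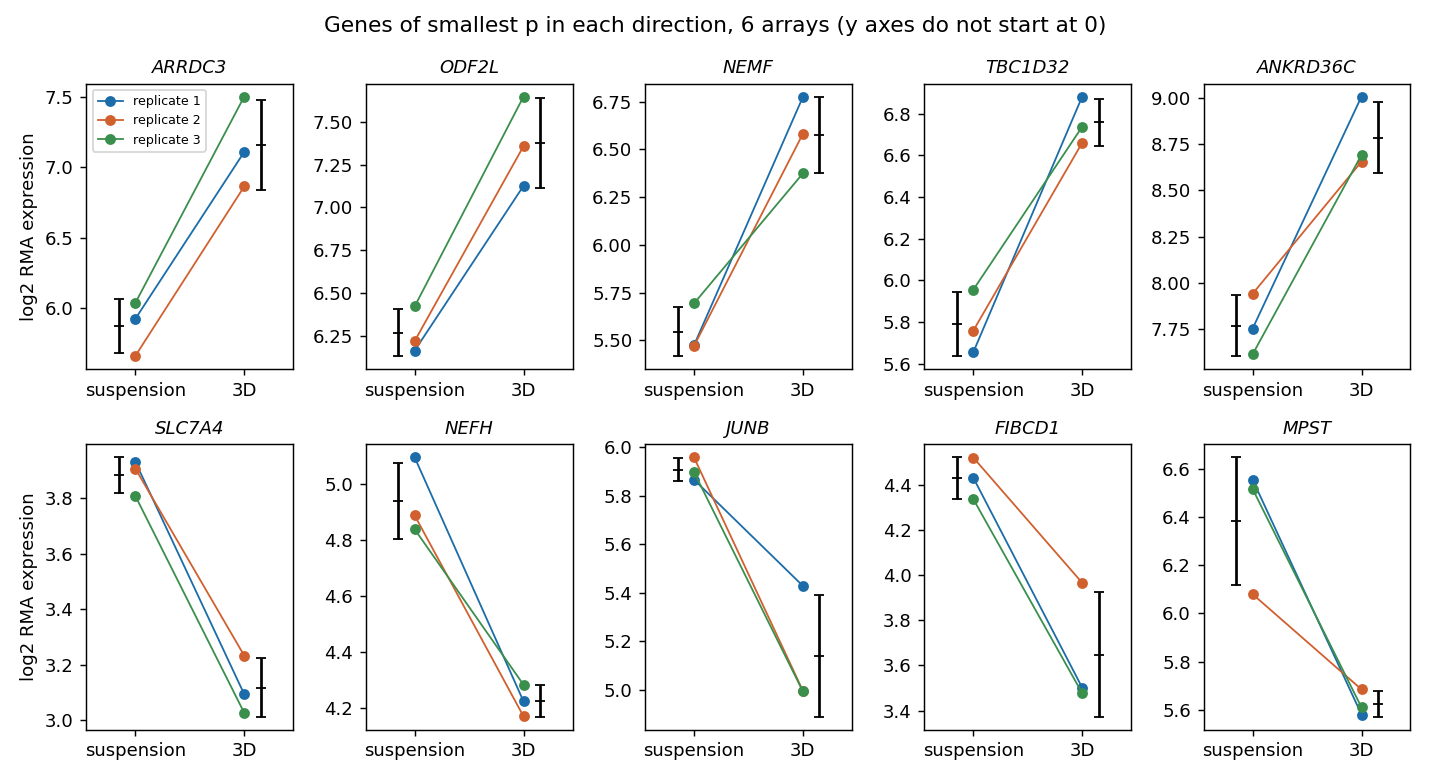
Log2 expression of the 5 genes of smallest p on each side, in suspension and 3D, with points for the 6 arrays, lines joining equal replicate numbers, and bars for the mean ± SD of 3 arrays. ARRDC3 lies at 5.87 ± 0.19 in suspension and 7.16 ± 0.32 in 3D, and in all 10 genes the groups do not overlap, though none has an adjusted p under 0.05 without the replicate block.

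With the replicate number as a block, 16 genes rose in 3D and 0 fell (limma, adjusted p 0.0344 to 0.0483). Their log2 differences ran from 0.97 to 1.36, and all 16 were higher in each of the 3 pairs. Without pair 1 the count was 19 higher and 2 lower, without pair 2 it was 132 and 18, and without pair 3 it was 35 and 1. The 16 genes called with all pairs were ABCA5, a lipid transporter gene (1.36, or 2.56-fold), ARRDC3, ACOT12, CCDC144A, MSH4, a meiotic recombination gene, ODF2L, the bitter taste receptor genes TAS2R4 and TAS2R19, AMY1C, ANKRD20A5P, CCDC191, ANKRD20A1, NEMF, RRH, ANKRD36C and TBC1D32. CCDC144A, AMY1C, the ANKRD20A genes, ANKRD36C and TAS2R19 belong to families with similar copies, so which copy gave the signal is uncertain, as probe sequences were not used here. The mean of 8 of the 16 lay under 6, the limit of a planned filter on dim probe sets. That of 14 lay under 7.05, the 90th percentile of 47 markers of cell types other than T cells. Of all genes 66.7% lay under this level, which is not a measured background. The lowest p-values on the falling side with the block were those of SLC7A4, FIBCD1 and FHL3, with adjusted p of 0.0660, 0.0672 and 0.0672. In the fit with the block limited to the 8342 genes of mean at or above 6, a setting chosen after the results were seen, 1199 genes passed, 884 higher and 315 lower, while without the block the same 8342 genes gave 0. That setting gave 331 higher and 127 lower without pair 1, 923 and 534 without pair 2, 369 and 37 without pair 3, and 650 and 425 after quantile normalization. Its fit had 2 residual and 25.0 prior degrees of freedom, so the spread was mostly shared between genes. Without the block the prior had 5.68 for these genes. The smallest difference called with the block had a size of 0.393.

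Differences between the groups varied with gene span. Among the fifth of genes with the shortest span the median log2 difference was -0.09, and among the fifth with the longest it was 0.06. Genes with few neighbours within 500 kb had a median difference of 0.07 and those with the most had -0.11. Across genes, which are not independent replicates, the difference had a Spearman correlation of 0.249 with span and of -0.277 with the number of neighbours. The slope of expression on span was higher in 3D than in suspension in each pair, by 0.13, 0.04 and 0.11 log2 per 10-fold span in replicates 1, 2 and 3. An exact two-sided permutation test over the 6 arrays gave p = 0.1, the smallest p that 3 against 3 allows. By chromosome, the genes of chromosome 19 had the lowest median difference (-0.13, 1256 genes) and those of chromosome 13 the highest (0.10, 290 genes).

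**Figure D2:**
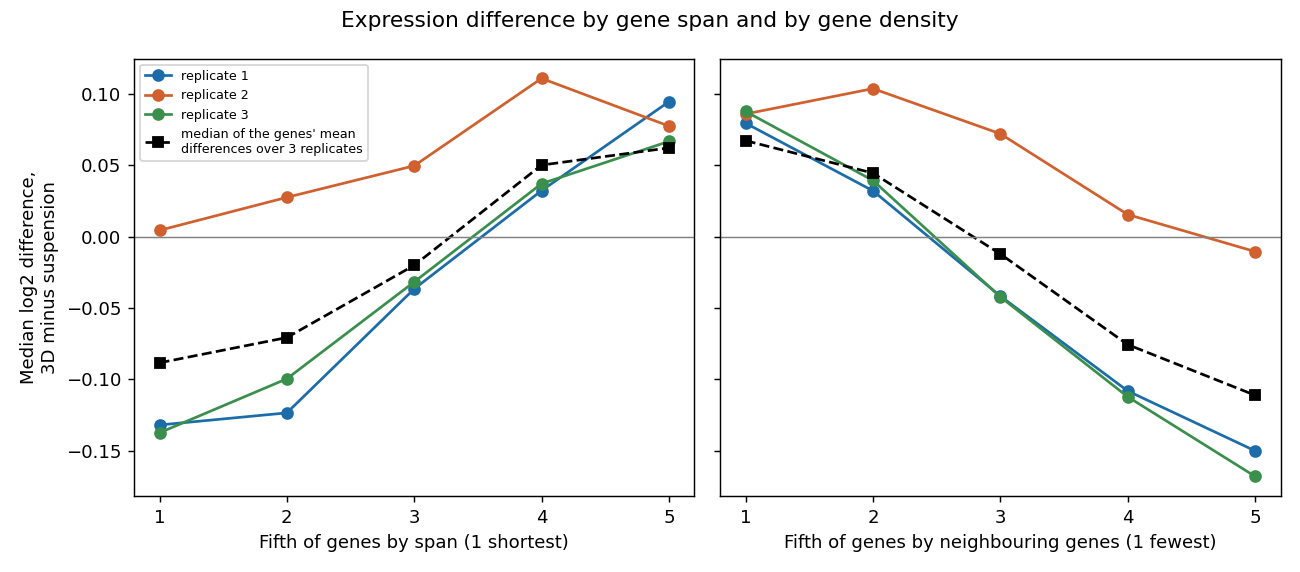
Median log2 difference, 3D minus suspension, for genes in 5 equal groups by span (left) and by number of neighbouring genes (right), with coloured lines for single replicates and a dashed line for each gene's mean over 3 replicates. The dashed line goes from -0.09 to 0.06 with span and from 0.07 to -0.11 with neighbours, and replicate 2 lies above replicates 1 and 3 in most groups.

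Immediate early genes, which encode transcription factors and feedback regulators induced within minutes of a stimulus, fell as a list in 3D. The median log2 difference of 30 measured members was -0.17, with 23 lower and 7 higher, and camera with a preset correlation of 0.01 gave an adjusted p of 0.0217 over 36 lists. The adjusted p was 0.957 with an estimated correlation. Of single members, 0 passed over all genes tested, and 1, JUNB, passed when adjusted over the list alone. JUNB measured 5.91 ± 0.05 (SD, n = 3) in suspension and 5.14 ± 0.25 (SD, n = 3) in 3D. The log2 difference was -0.55 ± 0.16 (SE) for MYC, -0.39 ± 0.16 for SRF and -0.38 ± 0.15 for FOSB. FOS and EGR1, picked here after their values were seen, had differences of -0.11 ± 0.20 and 0.05 ± 0.31. The list's median was -0.22 in replicate 1, 0.10 in replicate 2 and -0.31 in replicate 3. The call was lost without suspension replicate 3 (median -0.09, adjusted p 0.369), without 3D replicate 1 (median -0.14, adjusted p 0.0787), with camera on ranks (0.0597), with fry, a test of the list on its own (0.946), and with each array's trend on span and neighbours removed (0.159). With the block it was 0.00937, and 0.228 without pair 3 (median -0.09). Over all alternatives its adjusted p ran from 0.00225 to 0.957 without the block and from 0.00149 to 0.949 with it.

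Genes of G2 and mitosis were higher in 3D in every pair, and the call rested on the pairing. The median log2 difference of 29 measured members was 0.24, with 22 higher and 7 lower, and the medians per pair were 0.29, 0.31 and 0.22. Camera gave an adjusted p of 0.420 without the block and 0.00186 with the replicate number as a block. The adjusted p was 0.949 with the block and an estimated correlation. CCNA2, the cyclin A2 gene, had a log2 difference of 0.38 ± 0.21 (SE), KIF11, a spindle motor gene, 0.48 ± 0.30, TTK, a checkpoint kinase gene, 0.35 ± 0.24, and BUB1B 0.30 ± 0.21. Adjusted over the list alone, 0 members passed without the block and 5 passed with it, all higher; over all genes 0 passed either way. With the block and a mean at or above 6 the list was called neither without pair 2 nor without pair 3 (adjusted p 0.0687 for the latter), and over the alternatives with the block the adjusted p ran from 0.000941 to 0.949. The list's median level differed more between replicates than between groups. It was 7.98, 8.90 and 9.30 in suspension replicates 1, 2 and 3, and 8.30, 9.35 and 9.47 in the 3D replicates of the same numbers. Without the block the median turned to -0.15 when suspension replicate 1 was left out and reached 0.56 without 3D replicate 1, where the adjusted p was 9.08e-08. It was 0.00 without 3D replicate 3 (adjusted p 0.904) and 0.08 without 3D replicate 2 (0.701). Without suspension replicate 2 and without suspension replicate 3 it passed as well (adjusted p 0.0466 and 0.00127), and over all alternatives without the block the adjusted p ran from 9.08e-08 to 0.957.

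**Figure D3:**
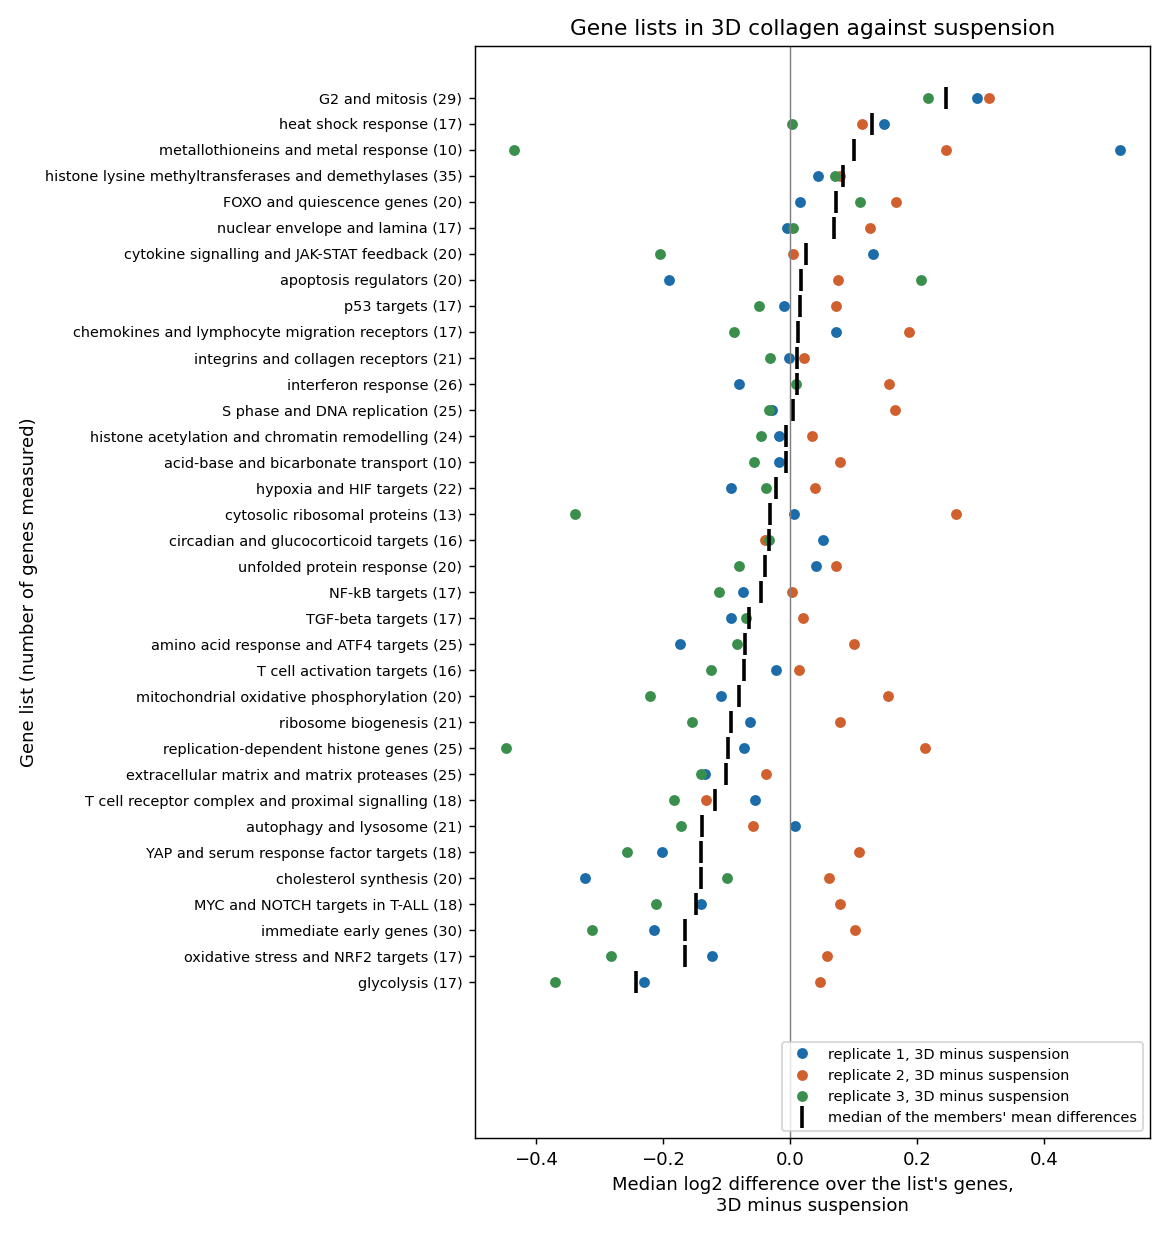
Median log2 difference, 3D minus suspension, over the measured genes of 35 of the 36 lists, with the number of genes in brackets, coloured points for the 3 replicates and black marks for the median of the members' mean differences. Immediate early genes lie at -0.17 and genes of G2 and mitosis at 0.24, the latter above 0 in every replicate.

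Other lists of growth and division did not pass camera. The list of S phase and DNA replication had a median log2 difference of 0.00 over 25 genes (adjusted p 0.693). It was the 1 list past fry's mixed test, which asks whether members change in either direction (adjusted p 0.000254), where 18 lists passed with the block. At an unadjusted p under 0.05, 2 of its members were higher and 0 lower. POLA1, the catalytic subunit of DNA polymerase alpha, was its 1 member to pass adjusted over the list alone, at 0.75 ± 0.16 (SE), with an adjusted p over all genes of 0.330. CLSPN, a replication checkpoint gene, had 0.52 ± 0.19, CDT1, a licensing factor gene, -0.35 ± 0.17, and MCM2, a helicase gene, -0.32 ± 0.15. Replication-dependent histone genes had a median of -0.10 over 25 genes (adjusted p 0.523), with -0.45 in replicate 3 and 0.21 in replicate 2. The list passed without suspension replicate 1 (median -0.19, adjusted p 0.00784) and without 3D replicate 2 (-0.24, 0.0163), over a range up to 0.957. With the block it passed without pair 2 (-0.28, 0.00640), over a range from 0.00217 to 0.979. The list of MYC and NOTCH targets stood at -0.15 over 18 genes (adjusted p 0.420), with NRARP, a NOTCH feedback gene, at -0.59 ± 0.18, HES4 at -0.44 ± 0.16 and NOTCH1 at -0.42 ± 0.19. With the block 3 of its members, all lower, passed adjusted over the list alone, where 0 did without it. FOXO and quiescence genes had a median of 0.07 over 20 genes (adjusted p 0.420), with 1 member, ARRDC3, passing adjusted over the list alone. Ribosome biogenesis (-0.09, 21 genes), p53 targets (0.02, 17 genes) and apoptosis regulators (0.02, 20 genes) had adjusted p of 0.886, 0.886 and 0.950.

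Among genes that meet the matrix, no list described here passed camera. Integrins and collagen receptors had a median log2 difference of 0.01 over 21 genes (camera adjusted p 0.950). DDR2, a collagen-binding receptor kinase, measured 3.91 ± 0.31 (SD, n = 3) in suspension and 4.63 ± 0.29 (SD, n = 3) in 3D, a difference of 0.72 ± 0.21 (SE). Both means lay under 6, the limit of the planned filter, and near 4.24, the median level of 47 markers of cell types other than T cells. Whether DDR2 was expressed at all is thus uncertain. ITGA6 and ITGA4, integrin alpha chains, had differences of 0.71 ± 0.30 and 0.46 ± 0.18, and LAIR1, an inhibitory collagen receptor, had -0.49 ± 0.21. None of the 4 passed over all genes (adjusted p 0.380 to 0.497). Adjusted over the list alone 0 passed, and with the block 4 did, 3 higher and 1 lower. Extracellular matrix and matrix protease genes had a median of -0.10 over 25 genes (adjusted p 0.420), with ADAM8 at -0.57 ± 0.16, cathepsin L (CTSL) at -0.49 ± 0.16 and ADAM17 at 0.34 ± 0.16. YAP and serum response factor targets stood at -0.14 over 18 genes (adjusted p 0.420), and TGF-beta targets at -0.06 over 17 (adjusted p 0.546). JUNB was the 1 TGF-beta target to pass adjusted over the list alone, and 3 passed with the block, 1 higher and 2 lower.

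The 3 lists of nuclear and chromatin genes did not pass camera. In the list of nuclear envelope and lamina (median log2 difference 0.07, 17 genes, adjusted p 0.545), TPR, a nuclear pore gene, had 0.66 ± 0.20 (SE), SYNE2, which links nucleus and cytoskeleton, 0.53 ± 0.19, and LMNA, the lamin A/C gene, -0.25 ± 0.16. With the block 2 members, both higher, passed adjusted over the list alone, against 0 without. Histone lysine methyltransferases and demethylases had a median of 0.08 over 35 genes (adjusted p 0.546). KDM4B, a histone demethylase gene, stood at -0.52 ± 0.17, and SUV39H2, a methyltransferase gene of H3K9, at 0.37 ± 0.16. The list of histone acetylation and chromatin remodelling had a median of -0.01 over 24 genes (adjusted p 0.952), with CHD7, a remodeller gene, at 0.58 ± 0.16 and SIRT2, a deacetylase gene, at -0.50 ± 0.20. Of these genes 0 passed over all genes tested.

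Lists of T cell genes did not pass in the test fixed for the comparison. The list of the T cell receptor complex and proximal signalling had a median log2 difference of -0.12 over 18 genes (camera adjusted p 0.420). CD247, the zeta chain of the receptor complex, had -0.52 ± 0.15 (SE), LCP2, the adaptor SLP-76, -0.51 ± 0.16, and PTPN22, a phosphatase that restrains receptor signalling, 0.66 ± 0.19, each with an adjusted p of 0.380 to 0.399. With the block 3 members passed adjusted over the list alone, 1 higher and 2 lower, and 0 without. The list passed in 1 of 15 settings with the block, at a mean at or above 6 without pair 1 (median -0.17, adjusted p 0.0475, range up to 0.949). T cell activation targets stood at -0.07 over 16 genes (adjusted p 0.604), with NFATC1 at -0.51 ± 0.20 and CD6 at -0.44 ± 0.19. Among NF-kB targets (-0.05, 17 genes, adjusted p 0.860) REL had 0.58 ± 0.24, and among interferon response genes (0.01, 26 genes, adjusted p 0.908) HLA-C had -0.55 ± 0.16 and DDX60 0.69 ± 0.21. Cytokine signalling (0.02, 20 genes) and chemokine and migration receptor genes (0.01, 17 genes) had adjusted p of 0.886 and 0.860. CXCR4, a chemokine receptor gene, had a difference of 0.16 ± 0.17.

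Markers of T cells and of B, myeloid, NK, stromal, endothelial or epithelial, and erythroid cells were compared between the groups. Of the 7 marker lists 0 passed camera. The 13 T cell markers had the smallest p, with a median log2 difference of -0.21 (unadjusted p 0.0297, adjusted p 0.208). Beside CD247, the differences of its members were -0.31 for CD3D, -0.44 for BCL11B, -0.30 for CD5, -0.28 for LCK, -0.25 for GATA3, -0.21 for CD2, -0.11 for CD7 and -0.08 for CD3E. They were 0.21 for LEF1, 0.11 for CD28, 0.08 for TRAT1 and 0.03 for CD3G. The adjusted p of the other marker lists ran from 0.260 for erythroid markers to 0.713 for endothelial or epithelial markers. With the block 1 stromal marker, lower in 3D, passed adjusted over its list alone, and 0 without.

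Lists of metabolism and stress gave no call in the test fixed for the comparison. Glycolysis genes had a median log2 difference of -0.24 over 17 genes (camera unadjusted p 0.0344, adjusted p 0.420), with -0.23, 0.05 and -0.37 in replicates 1, 2 and 3. The list passed in 5 of 15 settings with the block, among them without pair 2 (median -0.36, adjusted p 0.0129), and its adjusted p ran from 0.00217 to 0.949 over these and from 0.0635 to 0.957 without the block. ENO2 and PGAM1, glycolytic enzymes, had differences of -0.40 ± 0.20 (SE) and -0.34 ± 0.18. Cholesterol synthesis stood at -0.14 over 20 genes (adjusted p 0.420), with DHCR7, the enzyme of its last step, at -0.59 ± 0.18, and with 1 lower member passing adjusted over the list alone with the block and 0 without. The list passed without suspension replicate 1 (median -0.18, adjusted p 0.0403), where its alternatives without the block ran up to 0.957. Over these alternatives its median ran from -0.28 to 0.02. SLC7A11, the cystine transporter, had 0.49 ± 0.17 and belonged to both the amino acid response list (-0.07, 25 genes, adjusted p 0.821) and the oxidative stress list (-0.17, 17 genes, adjusted p 0.449). Heat shock genes had a median of 0.13 over 17 genes (adjusted p 0.546), with HSPH1, a chaperone of the Hsp110 family, at 0.68 ± 0.31 and HSPB1 at -0.40 ± 0.18. In the list of hypoxia and HIF targets (-0.02, 22 genes, adjusted p 0.727) PFKFB3, a regulator of glycolysis, had -0.46 ± 0.16. Autophagy and lysosome genes stood at -0.14 over 21 genes (adjusted p 0.546). With the block 6 of them passed adjusted over the list alone, 1 higher and 5 lower, and 0 without. The lists of mitochondrial oxidative phosphorylation (-0.08), the unfolded protein response (-0.04), cytosolic ribosomal proteins (-0.03), circadian and glucocorticoid targets (-0.03) and acid-base transport (-0.01) had adjusted p of 0.546, 0.893, 0.950, 0.893 and 0.693. Metallothioneins and metal response genes had a median of 0.10 over 10 genes (adjusted p 0.636), with 0.52, 0.25 and -0.44 in replicates 1, 2 and 3. With the block this list passed without pair 3 (median 0.38, adjusted p 0.00759), the lowest of a range up to 0.949. CLOCK, a core circadian gene, had 0.58 ± 0.17, and GPR65, a proton-sensing receptor gene, 0.69 ± 0.29. With the block 1 member, higher in 3D, passed adjusted over the list alone in each of the lists of heat shock, T cell activation, acid-base transport, circadian targets and interferon response, and 0 without. In the list of histone acetylation 2 higher members did so, and 0 without. Median and mean differed in sign for ribosome biogenesis, cytokine signalling, cytosolic ribosomal proteins, acid-base transport and histone acetylation, with means of 0.03, -0.05, 0.00, 0.10 and 0.00.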

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

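The pattern was seen before the comparison with level-matched probe sets was made. Probe sets without a gene name in the table used here, which are left out of the comparison of genes, were higher in 3D more often than named ones. At an unadjusted p under 0.05, 10.4% of 3739 unnamed probe sets were higher in 3D, against 5.75% of 17709 named ones. None passed limma's adjusted p without the block over all 21448 probe sets, with a smallest adjusted p of 0.0793 among the unnamed. Over all probe sets with the replicate block, 123 passed, of which 73 were unnamed and 72 of these higher. The median log2 difference of unnamed probe sets was 0.02, and it exceeded that of named probe sets of the same level by 0.0505 (SE 0.00831). In these arrays matching for level thus left this excess of the median in place. The share with an unadjusted p under 0.05 was not compared at matched levels, so a role of the lower level in that share stays open. The SE runs over probe sets of the same 6 arrays, which are not independent replicates. It holds no spread between cultures, so it does not say whether the excess would recur. What these probe sets detect was not analysed here, and no biological explanation was tested.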

How the results depend on the processing

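The settings that join the replicate block to a filter, a scaling, a left-out pair, trend removal or all probe sets, and trend removal alone, were chosen after the results were seen. The count of 0 genes held under all other planned settings without the block that use adjusted p, including each left-out replicate (lowest 0, highest 0). It became 16 with the replicate block and 23 when counting unadjusted p under 0.05 with a change of at least 2 times. The 14 added settings with the block gave 16 to 1457 genes: 16 with the trend on span and neighbours removed, 21 (19 higher, 2 lower), 150 (132 and 18) and 36 (35 and 1) without pair 1, 2 and 3, 123 over all probe sets, 753 over genes at or above the 40th percentile, and 1199 at a mean at or above 6. That last setting gave 814 with the trend removed, 458 (331 higher, 127 lower), 1457 (923 and 534) and 406 (369 and 37) without pair 1, 2 and 3, and 1075, 1105 and 1113 after quantile normalization, median centring and cyclic loess. Of its calls 73.7% were higher as deposited, 60.5% after quantile normalization (650 higher, 425 lower), 63.3% without pair 2 and 90.9% without pair 3. The cause of these differences was not tested. With the block the fit had 9.78 prior degrees of freedom over all genes and 25.0 at a mean at or above 6.

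Of 36 lists 1 passed. The count was 2 with the replicate block, 1 to 3 with 1 replicate left out, and 0 with the trend removed, an estimated correlation, ranks or fry. By fry's mixed test it was 1, and 18 with the block. With the block camera gave 1 with the trend removed (immediate early genes lost), 2, 4 and 2 without pair 1, 2 and 3, 2 with either filter, 0 with an estimated correlation, and, at a mean at or above 6, 2 with the trend removed, 3, 3 and 0 without pair 1, 2 and 3, and 3 after each of the scalings. Beyond immediate early and mitosis genes, these were glycolysis (after each scaling, and without pair 2 with and without the filter), histone genes (without pair 2 with and without the filter), the T cell receptor list (without pair 1, filtered) and metallothioneins (without pair 3, unfiltered). Without the block, histone genes passed without suspension 1 and without 3D 2, and cholesterol synthesis without suspension 1. The cause was not tested. Over 1179 comparisons of single lists, 10 calls were lost, 27 gained and 0 reversed. Over 4119 of the 156 named genes, 378 were gained, 0 lost and 0 reversed. Values not called changed sign in 163 and 41 of these. Beyond the calls named here and in the report, the replicate block changed no call of a list by camera or fry's directional test and no call of a gene named by rule except those among the 16. Signal over background was not measured, which limits what can be said of dim genes.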

Other observations

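The setting behind these first paragraphs, the replicate number as a block over genes of mean at or above 6, was chosen after the results were seen, as were its variants, and the tests of the patterns weighed here were written after the patterns themselves had been seen. Among 8342 genes limma called 1199 with it, 884 higher and 315 lower in 3D. These calls followed gene span, with a median of 57912 bases for higher, 12874 for lower and 30563 for all 8342 genes. Span was weighed as an explanation for the 16 and for the immediate early and mitosis lists, but not for these 1199 calls. With the trend removed, 814 were called. The changes were small, with a median log2 difference of 0.53 for higher and -0.47 for lower genes, and 8 genes at least 2-fold higher. Several fixed lists had members among them, all named after their values were seen. Of 28 genes of G2 and mitosis 7 were higher and 0 lower, among them the kinetochore genes CENPE (0.55) and CENPF (0.53), the spindle gene ASPM (0.55) and the motor gene KIF23 (0.47). Of 15 immediate early genes 3 were lower and 0 higher, namely MYC (-0.55), ZFP36 (-0.61) and IER2 (-0.40). ZFP36 was higher in pair 1 (0.09) and lower in pairs 2 and 3 (-0.53 and -1.39), and its groups overlapped. Without the block limma gave it an adjusted p of 0.459 over these genes. Of 15 integrins and collagen receptors 3 were higher, ITGA6, ITGA4 and RAP1A (0.41), and 2 lower, LAIR1 and FERMT3 (-0.42), which encodes the integrin activator kindlin-3. Among the members named here, the groups did not overlap for MYC and ITGA4 and overlapped for all others. CENPE measured 8.34 ± 1.52 (SD, n = 3) in suspension and 8.89 ± 1.42 in 3D. Without the block limma's adjusted p over the 8342 genes was 0.755 for CENPE, and the smallest of any gene was 0.222.

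In the same setting the T cell receptor list had PTPN22 higher and CD247 and LCP2 lower, among 18 genes, and the early activation gene CD69 was higher by 0.72 while CD6 was lower by a difference of -0.44. CD69 measured 5.67 ± 1.12 (SD, n = 3) in suspension and 6.38 ± 0.95 in 3D, and its groups overlapped. Without the block limma gave CD69 an adjusted p of 0.577 over the 8342 genes. Of 21 genes of ribosome biogenesis 4 were called higher and 0 lower, NOP58 (0.49), UTP20 (0.48), LTV1 (0.44) and UTP15 (0.44). The list as a whole did not rise, with a median of -0.09 and 12 of its members lower, called or not. Of all 8342 genes 884 were called higher. Of 16 glycolysis genes 0 were called, and of 32 histone lysine methyltransferases and demethylases 1. NOTCH1 (-0.42) and HES4 (-0.44) were lower. The groups overlapped for NOTCH1, as for NOP58, LTV1 and UTP15, and did not for HES4 and UTP20. Outside the lists the largest falls were FHL3 (-0.78), MPST and THAP11 (-0.72), and the largest rises beyond the 16 were TAS2R31 (1.27), CHD9, a chromatin remodeller gene (0.97), and SYCP2 (0.94).

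For the 16 genes that rose with the replicate block, the trend with gene span and neighbours was removed. Their median log2 difference was then 1.03 ± 0.04 (SE over the 16 genes, which are not independent replicates), from 1.07 before. Of these genes 13 were among the 16 then called. The trend was small, with medians from -0.11 to 0.07 in groups of genes by neighbours, and the 16 were picked by their calls. Removing it could therefore not have taken away rises of this size. The result shows only that the average trend is too small to make up their size. It does not decide whether what gave the trend also raised these genes. Of the 4 splits that part all 3 pairs, 1, the real one, reached 16 genes, with 0 as the highest of the others, and 1 reached 1199, with 0 as the highest other, but 4 splits are too few for a share under 0.05. Without the block all 10 splits of the 6 arrays gave 0 genes, and at an unadjusted p under 0.05 the real split gave 1745 genes against 1947 for the highest other, with 2 of 10 splits as large, where 10 splits are again too few. The split with 1947 kept replicate 1 of both groups together, and the other 3 splits that part all pairs gave 231, 517 and 297 genes, or 269, 710 and 373 with the block, against 3075 for the real one. An effect of collagen may underlie the calls, as may cross-hybridisation within multi-copy families or any difference in handling between the groups, and these stay open as untested.

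The second pattern is the fall of immediate early genes as a list. Of 10000 random lists matched on span, neighbours and level, 4.15% had a median as low as -0.17, which leaves these properties open as a candidate explanation: the members' median span was 5545 bases against 25888 for all genes. The camera p of 0.000603 was reached by 2 of 10 splits, too few splits for a share under 0.05, and the smallest of the others was 0.000561, in a split that also kept replicate 1 of both groups together. The other 3 splits that part all pairs gave p of 0.522, 0.00313 and 0.0444. The count of 1 list past the threshold was reached by 7 of 10 splits, with up to 9 lists, which points to a structure of the samples: the 4 splits that kept replicate 1 of both groups together gave 5 to 9 lists, and the other splits 0 to 4.

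For genes of G2 and mitosis with the replicate block, 0% of 10000 lists matched on span, neighbours and level had a median as high as 0.24. The list's members varied together without the block (estimated correlation 0.904), as those of random lists need not. With the block the estimate was 0.00143, resting on 2 residual degrees of freedom.

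The third pattern is the difference between genes of long and short span. The largest range of slopes on span within a group was 0.0587 log2 per 10-fold span, below the mean difference between groups of 0.0941 but above the 0.0406 of replicate 2, so differences between arrays unrelated to culture cannot be told apart from an effect of collagen. RNA quality or probe composition may give such a trend, and neither was measured here. With the trend removed 0 genes passed without the block, and the median of immediate early genes went from -0.17 to -0.13, with an adjusted p of 0.159 without the block, 0.0823 with it, and 0.0146 with it at a mean at or above 6 (median -0.18).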
